A study of Mus musculus with 30 samples.

How the data were processed

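RNA from 30 libraries of sorted mouse brain cells was analysed from the deposited files, 1 per library. Per the file headers, the count column gives the number of reads that aligned uniquely to each gene model, and the value column gives size-factor-adjusted RPKM. Per the submitters' processing notes, GSNAP and GRCm38 were used; their versions and the gene annotation are not given in the sources used here. The deposited counts were used in each test. The deposited RPKM values were used for a check alone, in which each library's values were its counts times 1 factor over gene length. Because reads had to align uniquely, genes with close copies, such as those of ribosomal proteins, are undercounted.

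Of 36528 gene identifiers, 31049 had a symbol in the GRCm38.p6 RefSeq table, and these held 96.7% of the counts. ID19791, which took up to 9.25% of a library's counts, had no symbol there. Groups were taken from genotype and cell type in the labels, and replicate numbers only name libraries. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 4.06). A count of 3 corresponded to 0.44 to 1.49 CPM.

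Each population was tested alone, PS2APP against non-Tg, in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM normalization, the quasi-likelihood test and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Fold changes are log2 PS2APP over non-Tg with SE. Differences between populations came from 1 edgeR fit of all 30 libraries. Of 40 gene lists fixed before the data were examined, those with at least 3 tested genes were tested by camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and by fry. Composition was compared by two-sided exact permutation tests in scipy 1.17.1. CPM within a population use that population's TMM factors, and CPM across populations use those of all libraries. On counts simulated from the myeloid libraries, edgeR recovered 45 of 100 genes changed 2-fold and 85 of 100 changed 4-fold with 4 false calls, and DESeq2 1.42.0 gave 21 false calls. The simulated counts held no library set apart from the others of its group.

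Named genes were fixed by rule before the data were examined: App, Psen2, Prnp and Thy1; the sort genes; per population up to 6 largest rises and falls among genes past the threshold with mean log2 CPM of at least 3, no overlap between groups and a full symbol; members of smallest p from the lists; and per difference the 3 of smallest p in each direction. Alternatives changed the normalization, filter, tool, fold threshold, covariates and libraries. Settings chosen after seeing the data were the tables without mitochondrial and ribosomal RNA genes, the mitochondrial share covariate, robust fits, and fits without the library farthest out on the first principal component. The tables without mitochondrial and ribosomal RNA genes also left out Malat1, Lars2, ID19791, Mir6236 and Gm15564, among others. Values of some genes that met these rules are not reported here.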

Results

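RNA was measured by sequencing in 30 libraries of brain cells from 11.5 month old mice. Each library held 1 of 3 sorted populations, NeuN+ neurons, Gfap+ astrocytes or Cd11b+ myeloid cells, from PS2APP transgenic mice or non-transgenic (non-Tg) littermates. PS2APP mice carry human presenilin 2 and amyloid precursor protein transgenes and form amyloid plaques. Each of the 6 groups had 5 libraries. The total count per library lay between 2015535 and 6749681. PS2APP myeloid libraries held 2473580 ± 413655 counts and non-Tg myeloid libraries 4704680 ± 1051810 (SD, n = 5 each), a difference beyond the spread between libraries (two-sided exact permutation p = 0.00794, adjusted p = 0.0476 over 24 tests). The labels do not say which libraries came from the same animal, so p-values measure the spread between these libraries.

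The sort genes followed the sort. Rbfox3, which encodes NeuN, stood at 121 ± 29.9 CPM in non-Tg neuron libraries, 11.4 ± 6.33 CPM in non-Tg astrocyte libraries and 6.87 ± 0.768 CPM in non-Tg myeloid libraries (SD, n = 5 each). Gfap, an intermediate filament of astrocytes, stood at 726 ± 168 CPM in non-Tg astrocyte libraries, 17.0 ± 4.87 CPM in non-Tg myeloid libraries and 3.58 ± 1.03 CPM in non-Tg neuron libraries. Itgam, which encodes Cd11b, stood at 1461 ± 190 CPM in non-Tg myeloid libraries, 5.76 ± 3.77 CPM in non-Tg astrocyte libraries and 7.22 ± 1.29 CPM in non-Tg neuron libraries. Marker totals of the other populations were present in each sort. The neuron markers summed to 754 CPM in non-Tg and 1139 CPM in PS2APP myeloid libraries, and to 1320 CPM in non-Tg and 2092 CPM in PS2APP astrocyte libraries.

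The first comparison asked which genes differ between PS2APP and non-Tg myeloid cells. Of 26 genes of the plaque-associated microglial state 13 rose, and of 20 genes of resting microglia 6 fell (camera adjusted p = 0.00057 and 0.16 with an estimated correlation). Gpnmb, a membrane glycoprotein of lipid-laden phagocytes, went from 0.15 ± 0.21 to 21.2 ± 4.67 CPM, and Cst7, a cysteine protease inhibitor, from 2.29 ± 1.47 to 84.0 ± 20.8 CPM (SD, n = 5 each). Apoe, a lipid carrier and Alzheimer's disease risk gene (chromosome 7, 19696244 to 19701310, GRCm38), rose from 167 ± 18.9 to 464 ± 96.4 CPM. Tmem119 and Cx3cr1, a surface marker and a chemokine receptor of resting microglia, fell from 629 ± 141 to 384 ± 105 CPM and from 1367 ± 204 to 916 ± 115 CPM, with calls kept in 3 of 10 leave-one-out fits each.

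In edgeR's quasi-likelihood test, 412 of 12274 genes passed an adjusted p of 0.05, 228 of them higher and 184 lower in PS2APP myeloid libraries. Of these, 99 rose and 70 fell at least 2-fold. The groups did not overlap for 4.80% of the genes tested, against 0.79% by chance. This share was also above 0.79% in astrocyte (2.99%) and neuron libraries (3.13%), where 26 and 1 genes passed, so alone it says little about the calls. The largest rises by the rule for named genes were those of Gpnmb, Arhgap6, Baiap2l2, Cst7, Ccl3 and Igf1. Arhgap6, a GTPase-activating protein, had a log2 fold change of 5.84 ± 0.57 (SE, edgeR adjusted p = 1.5e-06). Ccl3, a chemokine, had 3.22 ± 0.37 (edgeR adjusted p = 1.3e-05), and the growth factor Igf1 had 3.22 ± 0.38 (edgeR adjusted p = 1.8e-05). Baiap2l2, which shapes actin-rich membrane, went from 0.54 ± 0.82 to 25.9 ± 7.70 CPM. The largest falls were those of Ccr2, a chemokine receptor of monocytes (-2.16 ± 0.41), Alg11 (-2.07 ± 0.42), Kcp (-1.94 ± 0.49), Jpx (-1.76 ± 0.50), Tmem241 (-1.75 ± 0.34) and the clock output gene Dbp (-1.69 ± 0.42).

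**Figure D1:**
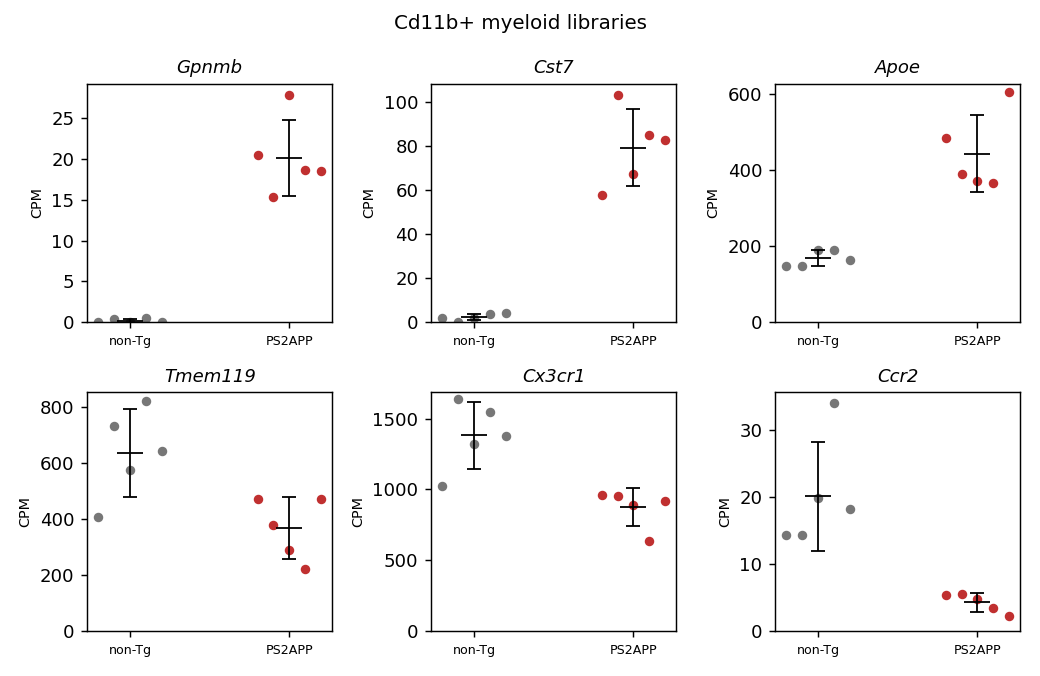
CPM, scaled over all 30 libraries, of 6 genes in the 5 non-Tg and 5 PS2APP myeloid libraries, each panel on its own linear axis from 0. Points are libraries and bars the mean ± SD, with Gpnmb, Cst7 and Apoe higher and Tmem119, Cx3cr1 and Ccr2 lower in PS2APP libraries.

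Of the 26 measured genes of the disease-associated microglia list, 13 rose, none fell and all 26 had a positive log2 fold change, with a median of 0.94. Adjusted over the list alone, 19 rose. It was the 1 list of 35 tested in myeloid libraries that passed camera both with the preset correlation (adjusted p = 1.2e-35) and with an estimated one (adjusted p = 0.00057 with an estimated correlation). Other members that rose, listed after their values were seen, were the lipase Lpl (3.07 ± 0.36), the growth factor Csf1 (1.85 ± 0.24), the integrin Itgax (2.07 ± 0.27), the receptor kinase Axl (1.68 ± 0.24), the lectin Clec7a (1.89 ± 0.47), Lilrb4a (0.94 ± 0.23), Ank (0.93 ± 0.26), Dkk2 and Tyrobp, an adaptor of Trem2 (0.64 ± 0.15). Of the 20 homeostatic microglia genes, 6 fell and none rose, or 10 fell and 1 rose adjusted over the list alone. Without PS2APP myeloid replicate 4, 2 of the 20 fell and none rose. By the rule for named genes, Tgfbr1, a receptor for TGF-beta, fell by 0.99 ± 0.20 on the log2 scale and Adgrg1 fell by 0.62 ± 0.14, beside Cx3cr1, Tmem119 and P2ry13, which were chosen after their values were seen and kept their calls in 3, 3 and 2 of 10 leave-one-out fits. That list passed camera (adjusted p = 1.2e-05), but not with an estimated correlation (adjusted p = 0.16).

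In all, 17 lists passed camera in myeloid libraries, and the other 16 lost the call with an estimated correlation (lowest adjusted p = 0.16). Of 20 interferon response genes, 3 rose and 1 fell (camera adjusted p = 0.00014, adjusted p = 0.28 with an estimated correlation). Stat2, which carries the type I interferon signal, rose by 0.98 ± 0.21 and the nucleic acid sensor Zbp1 by 1.78 ± 0.41, while Xaf1 fell by 1.32 ± 0.34. Nlrc5, the transactivator of MHC class I genes, rose by 1.87 ± 0.31 and was the 1 of 11 members of its list to do so. The glycolytic enzymes Pkm (0.81 ± 0.21) and Pfkl (0.87 ± 0.23) were the 2 of 17 glycolysis genes that rose. Of 9 MHC class II genes none passed, with H2-Ab1 at -0.91 ± 0.28 (edgeR adjusted p = 0.072). The chaperone Hsph1 rose by 1.39 ± 0.23.

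Genes of other cell types moved in the same libraries; Aqp4, Slc1a2 and Mbp were chosen after their values were seen. Gfap rose from 16.9 ± 4.64 to 116 ± 38.3 CPM (edgeR adjusted p = 5.0e-07), while Aqp4, a water channel of astrocyte endfeet, fell by 1.64 ± 0.41 and the glutamate transporter Slc1a2 stood at -0.11 ± 0.19 (edgeR adjusted p = 0.80). Of 20 glutamatergic synapse genes 3 rose: the kinase subunits Camk2a (0.97 ± 0.19) and Camk2b (0.94 ± 0.22) and the scaffold Shank1 (0.88 ± 0.22). That list lost its call with an estimated correlation (adjusted p = 0.20). The vesicle fusion genes Vamp2 (0.99 ± 0.23) and Stx1a (1.93 ± 0.45) and the myelin genes Mbp (0.84 ± 0.20) and Mobp (0.90 ± 0.20) rose as well, while of 8 oligodendrocyte markers 4 were positive and 4 negative (median 0.020, camera adjusted p = 0.10, adjusted p = 0.28 with an estimated correlation). Mitochondrial genes took 13.5 ± 2.97% of counts in PS2APP and 8.75 ± 2.89% in non-Tg myeloid libraries (exact permutation p = 0.056). The count of 412 was 105 without non-Tg myeloid replicate 4, 120 without replicate 5, 222 without replicate 3, 257 without replicate 2 and 652 without replicate 1 of that group, and 209, 189 and 216 without PS2APP myeloid replicates 3, 4 and 5. It was 124 with an other-cell covariate and 25 with the mitochondrial share as a covariate.

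With 1 myeloid library left out in turn, Gpnmb, Arhgap6, Baiap2l2, Cst7, Ccl3, Igf1, Apoe, Gfap, Thy1, Nlrc5, Hsph1, Lpl, Csf1, Itgax, Axl, Dkk2 and Camk2a kept their rise in all 10 edgeR fits, and Ccr2, Alg11, Tmem241 and Tgfbr1 their fall. Calls kept in 5 fits or fewer included those of Pfkl (1), App, Jpx and P2ry13 (2 each), Ank, Aplp2, Aqp4, Cx3cr1, Tmem119 and Xaf1 (3 each), Kcp, Pkm, Shank1 and Sparc (4 each), and Clec7a, Lilrb4a and Zbp1 (5 each). Adgrg1, Camk2b and Dbp kept theirs in 6, Mbp, Stat2, Stx1a and Vamp2 in 7, Tyrobp in 8 and Mobp in 9. Without non-Tg myeloid replicate 4 the edgeR adjusted p was 0.14 for Tmem119, 0.10 for Cx3cr1 and 0.12 for App.

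The second comparison asked the same of Gfap+ astrocytes. Of 22 reactive astrocyte genes 2 rose, and of 8 genes of MHC class I presentation 2 rose. Of the 26 genes called, 9 are abundant in the myeloid libraries. Abundant in myeloid libraries, here and below, means at least 50 CPM in PS2APP myeloid libraries and 20 times the non-Tg astrocyte level. Arhgap6 is among the 9, although it held at most 8.54 CPM in non-Tg myeloid libraries. C4b, a complement component, went from 386 ± 38.2 to 877 ± 197 CPM, and Aspg, an asparaginase of reactive astrocytes, from 26.2 ± 1.94 to 66.8 ± 17.5 CPM (SD, n = 5 each). C4a and C4b are near-identical neighbours on chromosome 17, so reads may have been split between them. ID102643089, also called, gained 549 CPM against 550 CPM for C4b, scaled over all libraries, and may share reads with C4b, which was not measured. C4b, C4a and ID102643089 are therefore not taken as separate signals among the 26 genes called. B2m, the light chain of MHC class I, rose from 10.1 ± 3.46 to 26.9 ± 4.35 CPM, a call kept in 3 of 10 leave-one-out fits.

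In edgeR's quasi-likelihood test, 26 of 14043 genes passed in astrocyte libraries, 26 of them higher and 0 lower, and 2415 had an unadjusted p under 0.05, of which 983 were lower. DESeq2 called 327 genes, 231 higher and 96 lower. By the rule for named genes the largest rises were those of Abi3 (2.96 ± 0.42), the phosphatase Inpp5d (2.28 ± 0.45), Rasal3 (2.87 ± 0.51), the colony-stimulating factor receptors Csf3r (2.77 ± 0.40) and Csf1r, and Nlrc5 (1.64 ± 0.32). Without PS2APP astrocyte replicate 3 the log2 fold change was 2.13 for Rasal3 and 2.15 for Csf3r, and both kept their calls. Csf1r stood at 9.66 ± 2.15 CPM in non-Tg and 27.3 ± 3.14 CPM in PS2APP astrocyte libraries. The other genes that rose, listed after their values were seen, included Sbno2, Gbp3, Rnf213, Dock6, Bcas1, Lrrfip1, Fcrls, Myo1f, Thy1, Arhgap6, C4a and the mitochondrial genes CYTB, ND4, ND1 and COX1. Mitochondrial genes took 6.91 ± 1.14% of counts in PS2APP and 3.58 ± 0.87% in non-Tg astrocyte libraries (exact permutation p = 0.00794, adjusted p = 0.0476).

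In astrocyte libraries 14 lists passed camera and none passed with an estimated correlation, the lowest adjusted p being 0.22. Of 22 reactive astrocyte genes 2 rose, C4b and Aspg, and 5 did adjusted over the list alone. Gfap itself stood at 0.82 ± 0.19 (edgeR adjusted p = 0.078). Of 8 MHC class I genes 2 rose, B2m and Nlrc5. Of 9 microglia markers 1 rose, Csf1r, and 4 did adjusted over the list alone. Of 20 cholesterol synthesis genes none passed, with Insig1 at -1.11 ± 0.30 (edgeR adjusted p = 0.12) and a list median of -0.45. Of 13 neuron markers none passed, with a list median of 0.73. Of 12 oligodendrocyte markers none passed, or 4 rose adjusted over the list alone, and 10 were positive (median 0.44, camera adjusted p = 0.0046, adjusted p = 0.35 with an estimated correlation). With 1 astrocyte library left out in turn, Abi3, Csf3r, C4b, C4a and Aspg kept their calls in all 10 edgeR fits, Arhgap6 and Sbno2 in 9, Csf1r, CYTB, ND1, ND4 and COX1 in 8, and Thy1 and Rasal3 in 7. Nlrc5 kept its call in 5, Fcrls, Gbp3, Lrrfip1 and Myo1f in 4, and B2m, Inpp5d, Bcas1, Dock6 and Rnf213 in 3. Without PS2APP astrocyte replicate 2 the edgeR adjusted p was 0.12 for B2m and for Nlrc5.

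The count of 26 was 8, 125 and 17 without non-Tg astrocyte replicates 2, 1 and 5, and 12 and 44 without PS2APP astrocyte replicates 2 and 1. With an other-cell covariate 3 genes passed, and none did with Xist or the mitochondrial share as a covariate, in edgeR as before.

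The third comparison asked the same of NeuN+ neurons. Kcnh7, a voltage-gated potassium channel subunit (chromosome 2, 62693410 to 63184287, GRCm38), was the 1 gene of 16064 that passed. It went from 220 ± 19.7 to 77.0 ± 4.80 CPM (SD, n = 5 each), a log2 fold change of -1.51 ± 0.11 (edgeR adjusted p = 3.6e-05). In the edgeR fit of all 30 libraries its effect did not pass as different between myeloid and neuron cells. The log2 difference there was 0.47 ± 0.42 (SE, edgeR adjusted p = 0.77). The fall of Kcnh7 was thus not shown to be particular to neurons. Genes with an unadjusted p under 0.05 numbered 3671, 1966 higher and 1705 lower, and DESeq2 called 153. In neuron libraries simulated with no library set apart, the edgeR test recovered 72 of 100 genes changed 2-fold. In the real ones the first principal component took 58.6% of the variance, with PS2APP neuron replicate 5 farthest out. This recovery may therefore not hold for them. The AMPA receptor subunit gene Gria2 stood at -0.42 ± 0.12, and Dlg4, the postsynaptic scaffold PSD-95, at 0.81 ± 0.25 (edgeR adjusted p = 0.19 for both). Of 21 glutamatergic synapse genes none passed, or 8 rose and 2 fell adjusted over the list alone. The list did not pass camera (adjusted p = 0.085, adjusted p = 0.73 with an estimated correlation). Gfap stood at 1.78 ± 0.26 on the log2 scale, from 4.12 ± 1.22 CPM in non-Tg libraries (edgeR adjusted p = 0.059). Of 21 oxidative phosphorylation genes none passed, with a list median of -0.33 (camera adjusted p = 0.015, adjusted p = 0.73 with an estimated correlation). Without PS2APP neuron replicate 5, 11 genes passed, among them Thy1 (edgeR adjusted p = 0.00039), Gfap (0.0041) and Arhgap6 (1.0e-05), and Kcnh7 passed in all 10 leave-one-out fits.

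Genes tied to the transgenes were compared in each population. Thy1, whose promoter drives many neuronal transgenes, rose in myeloid (2.14 ± 0.32, edgeR adjusted p = 0.00044) and astrocyte libraries (1.37 ± 0.24, edgeR adjusted p = 0.016), and stood at 1.31 ± 0.19 in neuron libraries (edgeR adjusted p = 0.059). App rose in myeloid libraries (0.68 ± 0.18, edgeR adjusted p = 0.043) and stood at 0.53 ± 0.24 in astrocyte and 0.39 ± 0.16 in neuron libraries (edgeR adjusted p = 0.27 and 0.20). The App call in myeloid libraries was lost in 8 of 10 leave-one-out fits, and without PS2APP neuron replicate 5 Thy1 passed in neuron libraries (edgeR adjusted p = 0.00039). Thy1 and App are expressed by neurons, and most neuron markers had positive log2 fold changes in the same libraries: 12 of 13 in myeloid libraries (median 0.54, camera adjusted p = 0.0019, adjusted p = 0.16 with an estimated correlation) and 11 of 13 in astrocyte libraries (median 0.73, camera adjusted p = 0.0011, adjusted p = 0.35 with an estimated correlation). Of them 1 was called in myeloid libraries, or 2 adjusted over the list alone, and none in astrocyte libraries, or 5 adjusted over the list alone. Their highest log2 fold change was 1.01 in myeloid and 1.72 in astrocyte libraries, against 2.14 and 1.37 for Thy1. In neuron libraries 16 neuron markers had a median of 0.068, against 1.31 for Thy1. The source of the higher Thy1 values was not tested. Psen2 stood at -0.13 ± 0.55, 0.75 ± 0.61 and 0.34 ± 0.19 in myeloid, astrocyte and neuron libraries, and Prnp at 0.67 ± 0.37, -0.40 ± 0.19 and 0.12 ± 0.26, and neither passed in any of them. Psen2 turned to -0.46 in astrocyte libraries without PS2APP astrocyte replicate 3, and with 1 library left out it lay between -0.55 and 0.19 in myeloid libraries, and Prnp between -0.042 and 0.30 in neuron libraries.

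Arhgap6 lies on chromosome X at 168795094 to 169304440 (GRCm38). It had a log2 fold change of 3.89 ± 0.61 in astrocyte libraries (edgeR adjusted p = 0.0083) and of 3.32 ± 0.52 in neuron libraries (edgeR adjusted p = 0.082). In each population 1 PS2APP library lacked the rise. PS2APP myeloid replicate 4 held 10.8 CPM against 338 to 569 CPM in the other PS2APP myeloid libraries, PS2APP astrocyte replicate 3 held 3.65 CPM against 72.9 to 211 CPM, and PS2APP neuron replicate 5 held 60.4 CPM against 287 to 888 CPM. These libraries were also those farthest out over all genes, at 97.2, 111 and 89.8 on the first principal component of their populations. The myeloid and the neuron library among them have adjacent sample identifiers. The labels do not say whether they came from the same animal. Without PS2APP neuron replicate 5 Arhgap6 passed in neuron libraries (edgeR adjusted p = 1.0e-05).

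**Figure D2:**
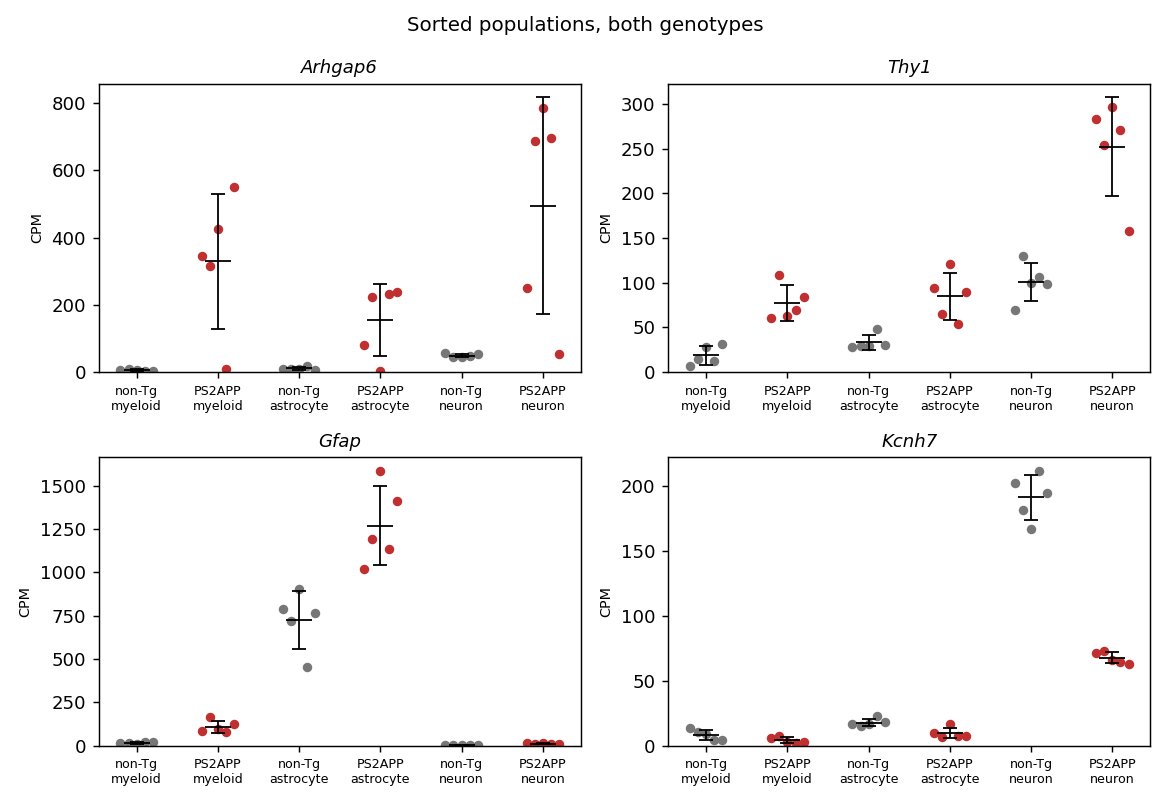
CPM, scaled over all 30 libraries, of Arhgap6, Thy1, Gfap and Kcnh7 in the 6 groups, on linear axes from 0, with points for the 5 libraries per group and bars for the mean ± SD. In each population 1 PS2APP library lies far below the others for Arhgap6, while Kcnh7 was lower in PS2APP neuron libraries.

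The difference of the PS2APP effect between populations was tested in a joint fit of 18101 genes. It passed for 137 genes between myeloid and astrocyte cells, 19 between myeloid and neuron cells and 6 between astrocyte and neuron cells. Gpnmb (log2 difference 6.62 ± 0.59), Cst7 (5.01 ± 0.66) and the motor protein gene Myo1e (1.97 ± 0.31) had a more positive effect in myeloid than in astrocyte cells, although Cst7 was too low to be tested in astrocyte libraries, and Abi3 (-3.04 ± 0.39), Fcrls (-3.09 ± 0.46) and Myo1f (-2.44 ± 0.36) a more negative one. Gpnmb (6.04 ± 0.65), Cst7 (4.98 ± 0.57) and Etl4 (2.51 ± 0.36) had a more positive effect in myeloid than in neuron cells, and Adgrg1 (-1.05 ± 0.21) a more negative one. Abi3 (2.57 ± 0.42), Myo1f (2.45 ± 0.43) and Ly9 (7.05 ± 1.26) had a more positive effect in astrocyte than in neuron cells. Of the 84 genes with a more negative effect in myeloid than in astrocyte cells 50 are abundant in myeloid libraries, as are all 6 of those between astrocyte and neuron cells. In non-Tg astrocyte libraries Abi3 stood at 4.06 ± 2.78 CPM and Myo1f at 1.40 ± 0.30 CPM, and 8 of 9 microglia markers were positive in astrocyte libraries. With only the 20 libraries of the populations compared, 51 genes passed between myeloid and astrocyte cells, and none between astrocyte and neuron cells. Without non-Tg myeloid replicate 2, 12 genes passed between myeloid and neuron cells; between astrocyte and neuron cells 1 passed without non-Tg neuron replicate 3, non-Tg astrocyte replicate 2 or non-Tg astrocyte replicate 4, 3 without PS2APP neuron replicate 1, 4 or 5, and 11 without PS2APP astrocyte replicate 5.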

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

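The tests of all patterns weighed here, the split counts included, were written down after the results they bear on had been seen. Intervals given with these tests are 95% bootstrap intervals over genes, so they do not measure the spread between libraries.

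Arhgap6 was higher in PS2APP libraries of all populations apart from 1 library in each, which was also the farthest out over all genes. The exceptions in myeloid and neuron libraries have adjacent sample identifiers, which the labels do not tie to an animal. A wrong genotype label on PS2APP myeloid replicate 4 is argued against: over 103 genes called without it, with the non-Tg mean at 0 and the other PS2APP libraries at 1, its median position was 1.27 (95% bootstrap interval 1.085 to 1.46). Of these genes, 93 lay nearer the other PS2APP libraries. This library also held the largest shares of Lars2 (4.08%) and ID19791 (9.25%), both among the 103 genes. It had the fewest genes detected (17097), so a position above 1 may partly reflect library quality, which was not tested. For PS2APP astrocyte replicate 3 (1.51 from 2 genes) and PS2APP neuron replicate 5 (-0.33, -0.57 to 1.08, from 5 genes) the label stays open, although Kcnh7 stood at 72.0 CPM in the latter against at least 195 CPM in non-Tg neuron libraries; Thy1 does not settle it, since neuronal RNA brings Thy1 and Snap25 was high in the former. The genes within 2 Mb of Arhgap6 had a median log2 fold change of 0.45, 0.91 and 0.87 in myeloid, astrocyte and neuron libraries. At most 0.033 of windows of as many neighbouring genes were as high, windows over the locus itself included. A variant or insertion at the locus, carried by some of the animals, may therefore account for the pattern, and an effect of the transgenes on Arhgap6 stays open as untested.

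Gfap was higher in PS2APP myeloid libraries. Astrocyte RNA or astrocytes in those libraries would bring the other abundant astrocyte genes along, but the median gain of 10 astrocyte markers over the gain needed was -0.14 (95% bootstrap interval -0.59 to 0.0042), which argues against them as the source. Astrocytes of unusually high Gfap content, and Gfap expression by the sorted cells, were not tested and stay open; the Cd11b+ sort would leave out most astrocytes.

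Genes abundant in myeloid libraries were higher in PS2APP astrocyte libraries. A shift in scaling from abundant mitochondrial and ribosomal RNA genes was weighed by leaving them out, with Malat1 and a few others. All 22 of the 26 genes called that stayed in the table were called again, so the calls did not need those genes. TMM trims extreme genes before scaling, so this removal could move the scaling little and cannot decide on such a shift. Myeloid RNA or cells would bring all abundant myeloid genes in 1 proportion, and the 20 most abundant of 306 such genes gained 1.13% of their myeloid level against 1.10% for the others, a ratio of 1.03 (0.763 to 1.36), which is consistent with carry-over, although Tmem119 gained -0.0049 ± 0.421% (SE). Carry-over may thus account, in whole or in part, for Abi3, Csf1r, Csf3r, Inpp5d, Rasal3, Fcrls and Myo1f, whose gains lay within 3 times the amount it brought. That amount ranged from 14.1 of the 30.7 CPM gained by Abi3 to 15.6 against 14.1 CPM gained by Inpp5d. For B2m it brought 2.66 of 18.9 CPM, which argues against it as the main source there. For the 17 other genes called, C4b, Aspg and Nlrc5 among them, it brought a median of 0.00904 of the gain seen (0.00179 to 0.0249). These 17 are the calls not abundant in myeloid libraries, so a low value followed from that choice and is no separate test. A myeloid share of 1.07% thus brings little of their gains. RNA of neurons or oligodendrocytes was not weighed for them, and an effect of genotype on astrocytes stays open. The 17 include C4a and ID102643089, which may share reads with C4b.

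Other splits of the same libraries were run for each count, and the splits giving as many include the real one. Of 100 splits, the highest other count of genes was 102 in myeloid libraries against 412 and 7 in astrocyte libraries against 26. In neuron libraries it was 2 against 1. Splits giving as many numbered 1, 1 and 3 in myeloid, astrocyte and neuron libraries. The real split thus stood alone in myeloid and astrocyte libraries, which argues against chance there. In neuron libraries other splits gave as many or more, so chance was not excluded. For gene lists with the preset correlation the highest other counts were 15 against 17 in myeloid and 16 against 14 in astrocyte libraries. There 1 and 3 splits gave as many. The myeloid count lay above those of all other splits drawn, which argues against chance with this correlation. The astrocyte count did not, so chance was not excluded. In neuron libraries 56 splits gave as many as 2, the highest other being 12, and chance was not excluded. With an estimated correlation the real split called 1 list in myeloid libraries, where the highest other called 2, and 0 of the 14 lists in astrocyte libraries, where the highest other called 1, so there the real astrocyte grouping gave no more lists than any other split. For the differences, 50 draws were made. Between myeloid and astrocyte cells 1 gave as many as 137 (highest other 11), which argues against chance. Between astrocyte and neuron cells 2 gave as many as 6 (highest other 35). Between myeloid and neuron cells 3 gave as many as 19 (highest other 773). For both of the latter chance was not excluded. Draws with 773 and 35 genes point to a structure of the samples, which was not examined.

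Of 222 groups of 5 libraries tested for a library far from the others, 19 held one, and chance gives about 1 in 20. Non-Tg myeloid replicate 1 had Baiap2l2 at 1.97 CPM against 0 to 0.413 CPM and Hsph1 at 108 CPM against 42.3 to 56.6 CPM in the other 4 libraries of its group. In PS2APP myeloid replicate 4, levels were Igf1 at 89.8 CPM against 32.3 to 41.3 CPM, Stx1a at 48.4 CPM against 11.2 to 21.7 CPM and Dkk2 at 16.6 CPM against 8.45 to 10.5 CPM in the other 4 libraries. Non-Tg myeloid replicate 2 had Adgrg1 at 424 CPM against 313 to 335 CPM in the other 4 libraries of its group. In non-Tg myeloid replicate 5, levels were Camk2a at 277 CPM against 133 to 165 CPM in the other 4 libraries. PS2APP myeloid replicate 5 had Hsph1 at 216 CPM against 135 to 147 CPM and Tyrobp at 354 CPM against 268 to 288 CPM in the other 4 libraries of its group. In PS2APP myeloid replicate 2, levels were Mbp at 1094 CPM against 618 to 719 CPM in the other 4 libraries. Non-Tg astrocyte replicate 4 had Thy1 at 41.3 CPM against 24 to 27.2 CPM, Psen2 at 9.1 CPM against 5.08 to 5.87 CPM and Insig1 at 41.6 CPM against 29.2 to 31.6 CPM in the other 4 libraries of its group. In PS2APP astrocyte replicate 3, levels were Psen2 at 34.6 CPM against 1.03 to 6.96 CPM, Rasal3 at 64.4 CPM against 11 to 17.1 CPM, Csf3r at 82 CPM against 18.5 to 25.8 CPM, Unc13a at 199 CPM against 97.3 to 116 CPM and Snap25 at 361 CPM against 66.9 to 150 CPM in the other 4 libraries. PS2APP astrocyte replicate 2 had Nlrc5 at 67.5 CPM against 25 to 37.3 CPM in the other 4 libraries of its group.

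The PS2APP effect on 32 values differed between populations in edgeR's joint fit, given as log2 differences. The effect was more positive in myeloid than in astrocyte cells for Gfap (1.88), Gpnmb (6.62), Cst7 (5.01), Apoe (1.26), Csf1 (1.40) and Axl (1.38), and more negative for Ccr2 (-3.84), Tyrobp (-2.50), H2-Ab1 (-5.28), Itgax (-3.90), Cx3cr1 (-1.66), Abi3 (-3.04), Rasal3 (-2.37), Csf3r (-2.27), Inpp5d (-2.09), Csf1r (-1.73), C1qb (-2.35), Ptprc (-2.22), Fcrls (-3.09) and Myo1f (-2.44). The effect was more positive in myeloid than in neuron cells for Gpnmb (6.04), Baiap2l2 (5.16), Cst7 (4.98), Igf1 (3.35), Lpl (3.39), Csf1 (1.58) and Dkk2 (6.25), and more negative for Adgrg1 (-1.05). The effect was more positive in astrocyte than in neuron cells for Abi3 (2.57), Csf3r (2.37), B2m (1.84) and Myo1f (2.45). Of the 84 genes with a negative difference between myeloid and astrocyte cells, 50 are abundant in myeloid libraries and 34 were too low to be tested in astrocyte libraries; the counts overlap, with Tyrobp in both, and leave out genes such as Sst (-3.41), which was chosen after its value was seen. The floor bears on positive differences too: 16 of 53 genes between myeloid and astrocyte cells, Cst7 among them, and 2 of 6 between astrocyte and neuron cells were not tested in astrocyte libraries, so the size of these differences is uncertain. The share of myeloid RNA weighed above (ratio 1.03) may account, in whole or in part, for the abundant genes, here and between astrocyte and neuron cells, apart from B2m. For those abundant genes the values are therefore not taken as different effects of PS2APP on the cell types, and for the other negative values this stays open.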

How the results depend on the processing

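Alternatives chosen after seeing the data were the tables without mitochondrial and ribosomal RNA genes, the mitochondrial share covariate, robust fits and the fits without the library farthest out on the first principal component; the others were planned. For the genes changed in myeloid cells, 412 as reported, no low count filter gave 939, DESeq2 899, limma-voom 747, all 30 libraries in 1 fit 798 (256 shared), the other-cell covariate 124, at least 2-fold 169 and the mitochondrial share covariate 25; leaving out 1 library gave 105 to 652. The split into 228 higher and 184 lower became 309 and 489 with all 30 libraries. For astrocytes, 26 as reported, no filter gave 514, DESeq2 327, limma-voom 274, all 30 libraries 295, the other-cell covariate 3 and both the Xist and the mitochondrial share covariate 0; leaving out 1 library gave 8 to 125. For neurons, 1 as reported, no filter gave 15, DESeq2 153, limma-voom 15, all 30 libraries 5 and the other-cell covariate 11; leaving out 1 library gave 1 to 11. The Xist covariate gave 4509 in neurons: with it the model took 0.648 of the variance of the first principal component, against 0.335 without, and 4269 of the 4509 genes followed that component (absolute r over 0.7) against 8182 of 16064 tested. Permuted Xist values gave a median of 1 gene and up to 3827 in 99 draws. For lists called, an estimated correlation gave 1 of 17, 0 of 14 and 0 of 2 in myeloid, astrocyte and neuron libraries, fry gave 10 and 5 in the first 2, and 5 lists were called in neurons without PS2APP neuron replicate 5, none of them with an estimated correlation (lowest adjusted p = 0.058). For the difference between myeloid and astrocyte cells, 137, no filter gave 213, limma-voom 18 and the 20 libraries 51; leaving out 1 library gave 103 to 176, and DESeq2 size factors turned 53 more positive and 84 more negative into 61 and 55. For myeloid against neuron cells, 19, leaving out 1 library gave 12 to 27, and adjacent identifiers as a replicate block, which the labels do not say share an animal, gave 12. For astrocyte against neuron cells, 6, the 20 libraries gave 0, leaving out the 3 farthest libraries 3, and leaving out 1 library 1 to 11. In each of these the cause was not tested. With 1 library left out, 4 genes that had not passed changed sign: Psen2 in myeloid (-0.55 to 0.19) and astrocyte libraries (-0.46 to 1.04), Slc1a2 in myeloid (-0.24 to 0.063) and Prnp in neuron libraries (-0.042 to 0.30). DESeq2 size factors in edgeR kept the call or its absence for 110 of 111 gene values and DESeq2 for 97. Scaling by library size alone shifted the median log2 fold change by -0.24, -0.18 and -0.17 in myeloid, astrocyte and neuron libraries. The alternatives planned for files without counts, such as another pseudocount, were not run, since the files hold counts. PS2APP myeloid libraries were the shallowest, and a count of 3 there was up to 1.49 CPM, which limits genes near that level.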

Other observations

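The values below were chosen after they were seen, and no explanation was tested for them. The unnamed gene ID19791 took 5.94 ± 2.12% of counts in PS2APP and 2.16 ± 0.63% in non-Tg myeloid libraries (SD, n = 5 each, two-sided exact permutation p = 0.00794, adjusted p = 0.0476 over 24 tests). Neutrophil markers in the myeloid sort summed to 697 ± 473 CPM in non-Tg and 404 ± 335 CPM in PS2APP libraries. In neuron libraries Slc17a6, a vesicular glutamate transporter of subcortical neurons, stood at -0.92 ± 0.23 and the calcium-binding protein gene Gca, which lies within 2 Mb of Kcnh7, at -1.28 ± 0.22 on the log2 scale (edgeR adjusted p = 0.19 and 0.13, n = 5 each). Of windows of as many neighbouring genes, 0.0151 had a median log2 fold change in neurons as low as the genes within 2 Mb of Kcnh7, -0.45.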
